A study of Mus musculus with 5 samples.

How the data were processed

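The study used chromatin immunoprecipitation followed by sequencing (ChIP-seq), which recovers and sequences the DNA bound by a chosen protein. The cells were AtT-20, a mouse pituitary line that serves as a model of corticotrophs, the cells that make ACTH. Per the labels' protocols, cells were treated for 20 min with leukemia inhibitory factor (LIF, a cytokine that signals through Stat3), with dexamethasone (Dex, a synthetic glucocorticoid that activates the glucocorticoid receptor, GR), or with both. Per the series' design text, 5 independent ChIPs were combined before library preparation for each condition. There are 5 libraries, 1 per group: Stat3 after LIF, Stat3 after Dex with LIF, GR after Dex with LIF, GR after Dex, and a control with non-specific IgG drawn from the different treatments. Reads of 36 bp were obtained on an Illumina GAIIx, per the labels' protocols. The Stat3 libraries combined antibodies against Stat3 and phosphorylated Stat3.

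The submitters' processing notes name the aligner Bowtie, the peak caller MACS 1.3.7.1 and the genome build mm9. The Bowtie version, the thresholds, how IgG was used, how the regions of different libraries were brought into 1 list and how they were sorted into clusters are not given in the sources used here. The labels of the 4 ChIP libraries name the same deposited list, which was the data used here. Per the file header, a track line without column names, it is a list of peaks by cluster. Each entry holds a chromosome, a position, a region number and a cluster number from 1 to 13. All 5670 entries have a start equal to their end, so each region is a point, and every position is a multiple of 5 bp. The region numbers run to 5874, and 204 of them (3.47%) have no entry in the list used here and were not analysed here, which can lower counts and break up groups of neighbours. Whether positions are counted from 0 or from 1 is not given, and they are printed as listed. The cluster number is a class assigned by the authors and not a measured quantity. The list read here gives no peak height, enrichment, p-value or value per library, so the sequencing depth and the IgG background are unknown here, and nothing ties a cluster number to Stat3, GR or a treatment.

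Because each condition is 1 library and the list pools them, no comparison between treatments, and no replicate error, could be computed. Every p-value below describes how the listed regions are arranged. Regions are not replicates of the experiment. The analyses of peak values, of shared and specific regions between treatments, of distance to transcription start sites, of DNA motifs and of nearest genes, which had been laid down before the data were examined, were not run. They needed values per library, or a genome and annotation of mm9, which were not used here. The only annotation at hand was a gene table of GRCm38, a different build, and its coordinates were not applied to mm9 positions. The fixed rule for naming genes (members of 9 preset gene lists nearest to a region, the genes with the most regions in each cluster, and Pomc and Socs3 in any case) therefore names no gene here. No gene, including Pomc and Socs3, was analysed here. Regions are given by position, and those named were chosen after their values were seen.

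Only the counts and shares per cluster follow an analysis fixed before the data were examined. The tests of chromosomes, spacing, neighbours and windows, with their distances of 10 kb, 100 kb and 500 kb, were chosen after a first look at the list that included trial permutations of the same quantities. Their p-values therefore describe patterns already seen in this list and are not those of tests set in advance. Shares of the list are given with exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. The length of a chromosome was taken as the span from its first to its last listed region. The number of regions per chromosome was set against the share of the summed span with a two-sided exact binomial test, with Benjamini-Hochberg adjustment over 20 chromosomes. Whether clusters differ in their spread over chromosomes was tested with a chi-square statistic and 100000 permutations of the cluster numbers. A region was called a neighbour of another when their positions lay at most 10 kb apart. Crowding was tested against 1000 sets in which each region was moved at random by up to 500 kb along its chromosome (one-sided). Which clusters lie beside each other was tested by permuting the cluster numbers over the fixed positions within each chromosome, 100000 times (two-sided). Adjustment was over 13 clusters or over 91 pairs of clusters, a cluster with itself included. The smallest p these permutations can give is 2e-05. The 10 windows of 100 kb with the most regions were taken without overlap, and their cluster makeup was set against all other regions with a two-sided Fisher's exact test, adjusted over 130 tests. The stretch around the fullest window was formed by linking regions up to 50 kb apart, a distance set after linking at 20 kb had split that window. The threshold was an adjusted p of 0.05.

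The neighbour test was tested on simulated data in which cluster numbers were shuffled over the 5670 real positions, with 10 simulations per setting. With no planted effect, 0 of 900 tests of pairs other than clusters 5 and 6 were called, and clusters 5 and 6 were called in 0 of 10. With 15 planted neighbouring pairs of clusters 5 and 6, this pair of clusters was called in 3 of 10 simulations. It was called in 10 of 10 with 30 and in 10 of 10 with 60. With 60 planted pairs, 3 of 900 tests of other pairs were called. A region could be drawn for more than 1 planted pair, so fewer planted pairs could remain. The simulated numbers were shuffled in the same way as in the test, so few calls without planting follow by construction. Cluster numbers that are alike over a stretch were not simulated. Merging overlapping or book-ended regions was the only alternative fixed before the data were examined that could be run. Other distances, permutation schemes and left-out loci were chosen after seeing the data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.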

Results

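The binding of Stat3, the transcription factor activated by LIF, and of GR, the glucocorticoid receptor, was mapped by ChIP-seq in AtT-20 corticotroph cells. The series sets Stat3 after LIF beside Stat3 after Dex with LIF, and GR after Dex beside GR after Dex with LIF, to relate the recruitment of the 2 factors to DNA. The 4 ChIP libraries and the IgG control were 1 library each. The deposited list used here holds 5670 regions on 20 chromosomes, each placed by the authors in 1 of 13 numbered clusters. The list carries no signal per library, so the clusters were compared by their size, their position in the genome and their neighbours, and not by factor or treatment. There were no replicates, and the tests of chromosomes, spacing, neighbours and windows were chosen after the list had been examined, so their p-values describe this list only.

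The regions were very unevenly divided among the clusters. Cluster 3 alone held 2465 regions, 43.5% of the list (95% interval 42.2% to 44.8%). Clusters 2, 6 and 7 were of similar size, with 658 regions (11.6%, interval 10.8% to 12.5%), 629 regions (11.1%, 10.3% to 11.9%) and 625 regions (11.02%, 10.2% to 11.9%). These 4 clusters together made up 77.2% of the list. Cluster 5 held 377 regions (6.65%, 6.01% to 7.33%) and cluster 4 held 332 (5.86%, 5.26% to 6.50%). The other 7 clusters had under 200 regions each and 10.3% of the list between them. Of these, cluster 1 had 198 regions, cluster 11 had 129, cluster 13 had 116, cluster 12 had 59, cluster 8 had 47, cluster 9 had 29 and cluster 10 had 6.

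**Figure D1:**
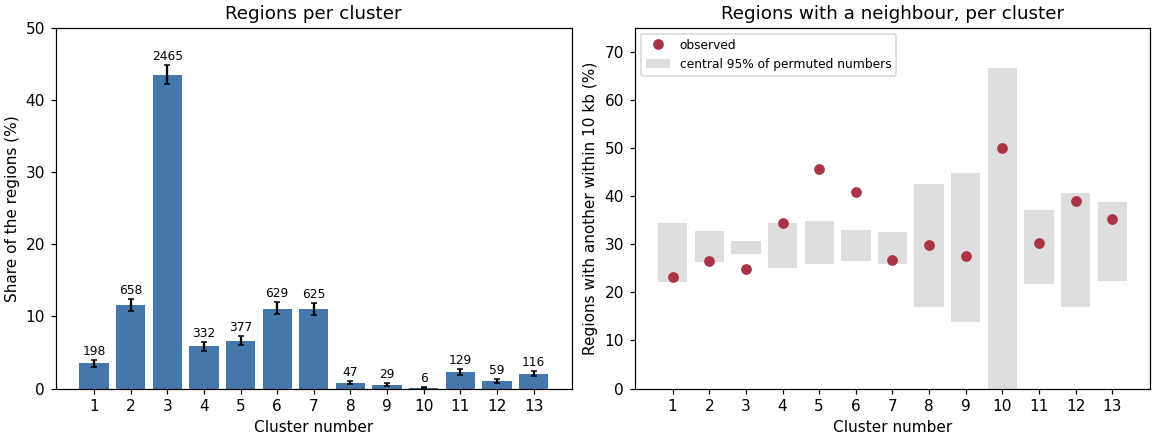
Left: share of the 5670 regions in each cluster (%), with exact 95% binomial intervals as error bars and the number of regions above each bar. Right: percentage of each cluster's regions that had another listed region within 10 kb (red points), with the central 95% of values from 100000 permutations of the cluster numbers (grey bars). Clusters 5 and 6, at 45.6% and 40.9%, lie above their grey bars and cluster 3, at 24.8%, lies below.

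Regions were most concentrated on chromosome 11 and most sparse on the X chromosome and chromosome 14. Chromosome 11 carried 512 regions, or 4.32 per Mb, which is 1.93 times its share of the summed chromosome spans (exact binomial test, adjusted p = 1.27e-42). The X chromosome carried 73 regions, 0.458 per Mb and 0.205 times its share (exact binomial test, adjusted p = 2.02e-76). Chromosome 14 carried 102 regions, 0.900 per Mb and 0.402 times its share (exact binomial test, adjusted p = 3.30e-27). Chromosomes 16, 10, 19, 2, 9 and 4 also lay above their share, at ratios of 1.43, 1.35, 1.28, 1.25, 1.17 and 1.14. Chromosomes 17, 13, 6, 3 and 1 lay below it, at 0.772, 0.773, 0.813, 0.834 and 0.874. The remaining 6 chromosomes did not pass the threshold. These p-values take each region as independent, although many had neighbours. With groups of neighbouring regions counted once, the ratio was 1.65 for chromosome 11, 0.240 for the X chromosome and 0.432 for chromosome 14. Counted so, the call for chromosome 1 was lost (ratio 0.927, exact binomial test, adjusted p = 0.192). The clusters themselves did not detectably differ in how they were spread over the chromosomes (chi-square 228, permutation p = 0.490). Mappability and copy number of the chromosomes were not used here.

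Listed regions were crowded together. The median distance from a region to the next was 111 kb, but 1670 regions, 29.5% of the list, had another within 10 kb. In sets moved at random by up to 500 kb this share averaged 10.6% and its central 95% ran from 9.56% to 11.7% (one-sided permutation p = 0.001, the smallest 1000 moved sets can give). Linked at 10 kb, the regions formed 4000 single regions and 710 groups of 2 or more, the largest with 10. The closest regions were 90 bp apart. Of the 329 pairs within 1 kb, 14 were under 200 bp apart.

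The most crowded part of the list lay on chromosome 11, where 23 regions fell between positions 117739795 and 117837540 (mm9). Of these, 20 belonged to cluster 3, 87.0% against 43.3% of all other regions (Fisher's exact test, adjusted p = 0.00286). Clusters 2, 4 and 13 had 1 region each there. In the 1000 moved sets, the fullest 100 kb window held 13 regions at most. Linking regions at 50 kb widened this stretch to 31 regions between 117597375 and 117895855, 25 of them in cluster 3. The second window lay on chromosome 10 between 59366145 and 59454095 and held 15 regions from 7 clusters. Cluster 6 had 6 of these and cluster 5 had 3, while cluster 3 had 1. The excess of cluster 6 (40.0% against 11.02% elsewhere, adjusted p = 0.0818) and the deficit of cluster 3 (6.67% against 43.6%, adjusted p = 0.0810) did not pass the threshold in Fisher's exact test.

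Windows with 11 regions followed on chromosome 2 (167583105 to 167677355) and on chromosome 10 (80377225 to 80457735). The window on chromosome 2 held 4 regions of cluster 4 and 3 of cluster 6. The second window of chromosome 10 held 4 regions of cluster 2 and 3 of cluster 6. On chromosome 8, 10 regions lay between 129259345 and 129353595 and 8 between 124372590 and 124437720, 4 of the latter in cluster 5. On chromosome 12, 9 regions lay between 103770565 and 103866615, and 5 of these were in cluster 6. The other windows among the 10 fullest lay on chromosome 1, with 9 regions between 74906225 and 74963235 and 8 between 137055845 and 137155275, and on chromosome 6, with 8 between 37298075 and 37378600. Of 130 tests of a cluster in a window, the excess of cluster 3 on chromosome 11 was the only one to pass the threshold. No annotation of mm9 was used here, so the genes, exons or introns at these positions are not stated.

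**Figure D2:**
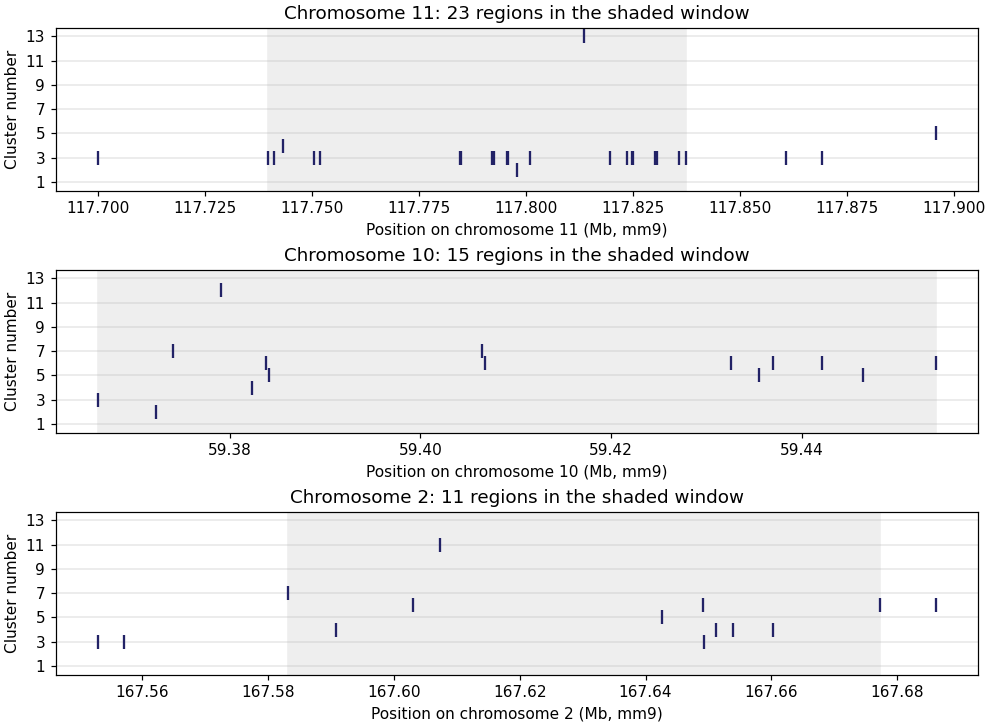
Regions in the 3 fullest windows of 100 kb, by position (x axis, Mb on mm9) and cluster number (y axis). Each tick is 1 region and the shaded part is the window. The window on chromosome 11 is filled mostly by cluster 3, with 20 of 23 regions, and those on chromosomes 10 and 2 hold regions of 7 and 6 clusters.

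Clusters differed in how often their regions had neighbours. In cluster 5, 45.6% of regions (172 of 377, 95% interval 40.5% to 50.8%) had another region of any cluster within 10 kb, against 30.3% expected from permuted cluster numbers (permutation test, adjusted p = 8.67e-05). In cluster 6 the share was 40.9% (257 of 629, interval 37.0% to 44.8%) against 29.8% (permutation test, adjusted p = 8.67e-05). In cluster 3 it was 24.8% (612 of 2465, interval 23.1% to 26.6%) against 29.3% (permutation test, adjusted p = 8.67e-05). These are the smallest adjusted values the permutations gave. The other 10 clusters did not pass the threshold. Cluster 4 had 34.3% against 29.7% (permutation test, adjusted p = 0.164), and the small clusters 8, 9 and 10 had wide intervals (17.3% to 44.9%, 12.7% to 47.2% and 11.8% to 88.2%).

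Cluster 5 lay beside clusters 4 and 6, and clusters 5 and 6 each beside itself, more often than their sizes and chromosomes gave. Among the 1240 pairs of regions within 10 kb, 61 joined cluster 5 with cluster 6, against 19.7 expected (central 95% 11 to 29), a ratio of 3.10. Cluster 5 neighboured itself in 29 pairs against 6.06 (2 to 12), a ratio of 4.78. Cluster 6 neighboured itself in 51 pairs against 15.7 (8 to 24), a ratio of 3.25. Clusters 4 and 5 met in 31 pairs against 10.3 (4 to 17), a ratio of 3.00. The adjusted permutation p was 0.000303 for each of these 4. With pairs within 1 kb left out, the ratio was 3.42 for cluster 5 with itself, on 15 pairs. It was 2.35 for clusters 5 and 6, 3.27 for cluster 6 with itself and 2.65 for clusters 4 and 5. When cluster numbers were permuted among regions with neighbours only, the ratios were 1.49 for clusters 5 and 6, 2.13 for cluster 5 with itself, 1.73 for cluster 6 with itself and 1.77 for clusters 4 and 5, and the highest adjusted permutation p of these was 0.0344. Clusters 4 and 6 met in 28 pairs against 16.6, which did not pass the threshold (permutation test, adjusted p = 0.118), and cluster 4 met itself in 10 against 4.42, which did not pass it either (adjusted p = 0.228).

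Cluster 3 showed the opposite relation to clusters 6 and 7. It met cluster 7 in 57 pairs against 116 expected (95 to 139), a ratio of 0.490, and cluster 6 in 71 pairs against 120 (98 to 143), a ratio of 0.590 (adjusted permutation p = 0.000303 for both). It met cluster 2 in 87 pairs against 126 (103 to 149), a ratio of 0.691 (permutation test, adjusted p = 0.00748). This last deficit was no longer called when each group of neighbours was counted once (ratio 0.783, adjusted permutation p = 0.0819), and it was 0.929 (adjusted p = 1) when cluster numbers were permuted among regions with neighbours only. Cluster 3 met itself in 246 pairs against 232 (202 to 264), a difference within the spread when all regions were permuted. Because cluster 3 regions had neighbours less often, this does not settle whether those with neighbours lie beside each other. The count expected for cluster 3 with itself when only regions with neighbours were permuted is not given here. Under that permutation the ratio for all same-cluster pairs together was 1.55.

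**Figure D3:**
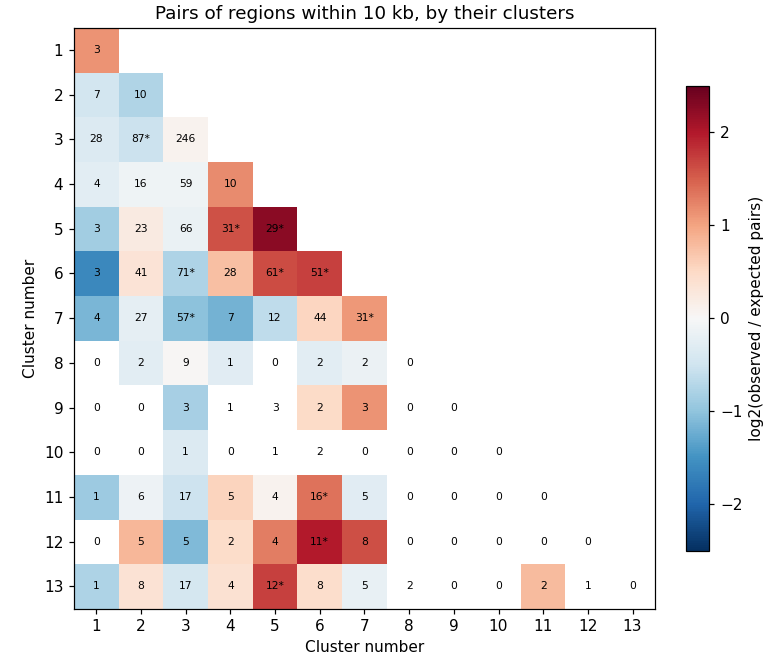
Number of pairs of regions within 10 kb for each pair of clusters, with color showing log2 of observed over expected pairs and an asterisk where the adjusted permutation p was under 0.05. Cells are left uncolored where under 1 pair was expected or 0 were observed. The excess was called for clusters 5 and 6 (61 pairs), clusters 4 and 5, and clusters 5 and 6 each with itself, and cluster 3 has fewer pairs with clusters 6 and 7.

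In all, 8 of the 91 pairs of clusters were called as more frequent neighbours and 3 as less frequent. The other 4 called as more frequent were cluster 7 with itself (31 pairs against 14.6, adjusted p = 0.00748), clusters 6 and 12 (11 against 2.79, adjusted p = 0.00748), clusters 5 and 13 (12 against 3.67, adjusted p = 0.0115) and clusters 6 and 11 (16 against 6.25, adjusted p = 0.0194), all by permutation. Counted once per group of neighbours, clusters 5 and 13 (ratio 2.65 after 3.27, adjusted permutation p = 0.0799) and clusters 6 and 11 (ratio 2.06 after 2.56, adjusted p = 0.151) were no longer called, though their ratios stayed above 1. With only regions with neighbours permuted, their ratios were 1.82 and 1.75 (adjusted permutation p = 0.359 and 0.238). Each of these 2 pairs of clusters passed the threshold under 4 of 10 alternatives. Clusters 6 and 12 were no longer called when pairs within 1 kb were left out (ratio 2.43 on 5 pairs, adjusted permutation p = 0.528) or when regions with neighbours only were permuted (ratio 2.04, adjusted p = 0.223). Cluster 7 with itself was at a ratio of 2.12 within 10 kb, 1.38 within 50 kb (adjusted permutation p = 0.193) and 1.12 within 100 kb (adjusted p = 0.932). Without pairs within 1 kb its ratio was 2.06, with fewer pairs and an adjusted permutation p of 0.0648. With only regions with neighbours permuted, its ratio was 2.31 (31 pairs against 13.4, adjusted permutation p = 0.00364). Cluster 7 with itself passed the threshold under 6 of 10 alternatives.

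Pairs of the same cluster made up 30.6% of all pairs within 10 kb (380 of 1240), against 23.6% expected, a ratio of 1.301 (permutation p = 2e-05). By distance, the share was 36.8% in the 193 pairs up to 0.5 kb apart, against 23.5% expected (permutation test, adjusted p = 0.0018). The excess did not fall steadily with distance. It was also called at 1 to 2 kb (32.9% against 23.4%, adjusted permutation p = 0.0158), 5 to 10 kb (30.4% against 23.6%, adjusted p = 0.0075), 20 to 50 kb (27.7% against 23.6%, adjusted p = 0.0081) and 50 to 100 kb (27.3% against 23.5%, adjusted p = 0.0075). It was not called at 0.5 to 1 kb (27.9%, adjusted permutation p = 0.323), 2 to 5 kb (27.4%, adjusted p = 0.180), 10 to 20 kb (23.9%, adjusted p = 0.921) or 100 to 200 kb (24.96%, adjusted p = 0.171). Without the 31 regions of the chromosome 11 stretch, only the excess at up to 0.5 kb passed the threshold among these 9 distances (34.8% against 23.2%, adjusted permutation p = 0.0027). The share without them was 30.7% against 23.3% at 1 to 2 kb, a ratio of 1.32 after 1.40 with all regions, so the call there was lost with little change in size. It was 26.1% against 23.1% at 5 to 10 kb, 23.2% against 23.3% at 20 to 50 kb and 24.8% against 23.3% at 50 to 100 kb.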

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

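All alternatives reported here except the merging of overlapping or book-ended regions were chosen after seeing the data. Merging overlapping or book-ended regions changed no cluster count, since no regions share a position. Merging regions of the same cluster within 500 bp or 1 kb changed no count by as much as 1.5 times, and cluster 3 went from 2465 to 2427 or 2398. The excess of clusters 5 and 6, of cluster 5 with itself, of cluster 6 with itself and of clusters 4 and 5 passed the threshold under all 10 alternatives, as did the deficit of clusters 3 and 7. Their size depended on the setting. For clusters 3 and 7 the ratio ran from 0.289 within 1 kb to 0.664 with only regions with neighbours permuted. The ratio ran from 1.49 to 5.13 for clusters 5 and 6, from 2.13 to 8.47 for cluster 5 with itself, from 1.73 to 3.42 for cluster 6 with itself and from 1.77 to 3.95 for clusters 4 and 5. For these 4 excesses the lowest value came from permuting only regions with neighbours. The deficit of clusters 3 and 6 passed under 9 of 10 and missed it for pairs within 1 kb (ratio 0.536, permutation test, adjusted p = 0.0507). With pairs within 1 kb, 5 pairs of clusters were called as more frequent and 1 as less frequent, and the ratio for clusters 6 and 11 reversed to 0.608, on 1 pair. With pairs over 1 kb and up to 10 kb, 5 were called as more frequent. With only regions with neighbours permuted, 6 were called as more frequent and 4 as less frequent. Some calls of each kind were for pairs of clusters not called when all regions were permuted. Pairs within 100 kb gave 7 calls of less frequent neighbours. Clusters whose regions had neighbours more or less often than chance numbered 4 at 1 kb, 3 at 10 kb, 6 at 50 kb and 7 at 100 kb. More pairs enter at longer distances and fewer at shorter ones, but the numbers of calls did not follow this throughout. The cause was not tested. Crowding kept its direction and its call under 6 alternatives, at ratios to the moved positions from 1.37 (within 50 kb) to 9.38 (within 1 kb), with 2.77 reported at 10 kb. The same-cluster ratio was 1.22 without the densest stretch, 1.24 without the 10 densest windows and 1.55 when only regions with neighbours were permuted. The alternatives set before the data were examined on overlap fractions, peak thresholds, promoter windows, motif windows and gene distances were not run, because point positions without values, genome or annotation of mm9 give them no value. The unknown depth of the libraries limits every count of regions, since it sets how many regions a caller can list.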

Other observations

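All tests in this part were chosen after the results were seen. The excess of neighbours among clusters 4, 5 and 6 was weighed by choosing pairs of clusters on one set of 10 chromosomes and counting them on the other 10, both ways, since the excess had been found on the same list. The 4 pairs of clusters (4 with 5, 5 with 5, 5 with 6, and 6 with 6) were called in each set. Clusters 5 with 13 and 6 with 11 were called in the first set only, and 6 with 12 in the second only. Cluster 7 with itself was called in neither. All chosen pairs together had a ratio of 3.12 within 10 kb on the other chromosomes (182 against 58.3 expected, central 95% 43 to 75). This ratio was 1.65 when only regions with neighbours were permuted, and it was not computed for each pair of clusters. If the authors sorted regions by signal in a window around each point, overlapping windows could place close neighbours in like clusters. Windows up to 20 kb wide would not overlap at 20 to 50 kb, where the ratio was 2.18 (153 against 70.1, central 95% 52 to 89). It was 1.44 there when only regions with another at 20 to 50 kb were permuted (against 106.6, 89 to 125). These values do not settle the excess within 10 kb. Regions of clusters 5 and 6 had neighbours more often, and the number of neighbours per region was not matched. Crowding and overlap therefore cannot be told apart by these counts. Overlap remains open, also because the width of any window is not given in the sources used here. Without the 10 densest windows and the chromosome 11 stretch, the ratio within 10 kb was 3.18 (155 against 48.7, central 95% 35 to 63). This argues against those loci as the whole cause. The windows were ranked by regions of all clusters, so loci crowded with clusters 4, 5 and 6 were not left out as such. Permutation among regions with neighbours only was not run for this set. Whether these clusters share a factor or a treatment was not tested, because the cluster numbers are not tied to the libraries here.

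For the crowded stretch of chromosome 11, the fullest window over 1000 sets of moved positions held 13 regions against the 23 observed. This argues against chance placement of regions independent of each other. The second window, on chromosome 10, held 15 regions and also exceeded 13, and the list as a whole was crowded against these sets. They therefore cannot show whether the stretch goes beyond the crowding found across the list. Extra copies of a wider segment in AtT-20 cells, which raise reads in any library, remain open. The 500 kb before the stretch held 4 regions and the 500 kb after it 7, and the exact Poisson 95% interval of these 11 over 1 Mb (5.49 to 19.7) lay above the 4.07 per Mb of the rest of chromosome 11, which is what extra copies had been set to show. This does not settle it, because the interval takes regions as independent although they are crowded, and because copy number and IgG signal were not measured here. No biological explanation was tested.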
